A study of Danio rerio with 49 samples.

How the data were processed

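The series profiled chromatin in zebrafish sperm, in embryos at 2.5 hours post fertilization, before activation of the zygotic genome (called preZGA in the labels), and in embryos at the sphere stage, after activation (postZGA). ChIP-seq was made for the histone variant H2AZ and for H3K4me1, H3K4me3, H3K14ac, H3K27ac and H3K27me3, in wild-type fish and in fish lacking anp32e, whose product is a histone chaperone that removes H2AZ from nucleosomes. Chromatin was fixed with 2.2% formaldehyde, per the labels. Of the 49 samples, 40 stand behind the 17 peak lists used here, and each list joins the 2 or 3 libraries of its group. The other 9 samples (4 inputs, 3 haploid-embryo H2AZ samples and 2 null sphere H3K4me1 samples) were not analysed here.

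Novoalign 2.8 and MACS2, with no version named, are listed in the submitters' processing notes. Per the file and track names, the authors divided the pooled signal by an input background, took the log10 of that fold and kept places above 3-fold. The lists show the outcome of this filter. No peak was shorter than 100 bp, and the smallest gap between neighbouring peaks was 101 bp. In 15 lists the authors deposited a score per peak, read here from the track names and the values as the whole part of 10 times the log10 fold over input. The lowest score was 4, and a score of 8 stands for at least 6.31-fold. The score is the authors' own value and was used to describe, rank and filter peaks. Where the same score cut is applied to separate lists, and where heights in mutants are set against wild type, the scores of separate lists are set on a common scale, which different inputs could distort. The sphere lists of the null and of the paternal null gave no score. The sources used here do not say which input went with which list. The labels name an embryo input mixed from preZGA and postZGA wild-type embryos, an input of haploid sphere embryos, and separate sperm inputs for wild type and null.

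The lists hold positions, not reads, so the depth of each library is unknown here, and so is its effect on how many peaks were called. Because a list pools its replicates, no spread between replicates can be had. No test across replicates was run, no p-value is given, and a difference between lists is a difference between those lists. Shares of peaks carry exact 95% Clopper-Pearson intervals, which cover counting error only, since neighbouring peaks are not independent.

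Peaks were compared on the 25 chromosomes, with at least 1 bp shared counting as overlap. Each list was also moved 1000 times by seeded random distances along its own chromosomes, wrapping at the ends, and the overlap was counted again. The mean of these shifted positions is the chance level given beside the shares. For the preZGA H3K27ac list 200 shifts were made. For the main comparisons, 198 pairs of lists or parts of lists were set against shifts. Peak positions are counted from 1. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The overlap code was tested on simulated data, 2 lists with 7500 peaks and a planted overlap of 40%, and recovered 40.0%.

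The genome build of the lists is not given in the sources used here. The gene table at hand is of the GRCz12tu assembly, and a check fixed before the data were examined showed that the lists lie on another build. On 24 of the 25 chromosomes the last gene of the table lies past the last peak of all lists. Only 8.53% of sperm H3K4me3 peaks lay within 1 kb of a gene end, against a mean of 8.38% and a highest value of 8.81% after 200 shifts. For this reason the planned counts of promoters and the 13 planned gene lists were not run, and no gene is named from a position. By the rule fixed for that case, named regions are the 5 widest gained and the 5 widest lost peaks of each comparison. The widest peaks of sperm marks were named by the same size rule, chosen after the data were seen. Gained means present in the later or mutant list with no overlap in the other, and lost means the reverse.

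The paternal null sphere list holds no peaks on chromosomes 1, 2, 3, 8 and 9 and covers only the start of chromosome 4. Its peaks there were not analysed here. Every comparison with this list was therefore limited to the 19 chromosomes on which it spans at least 90% of the length covered by the other lists. The design had set no such limit. The limit was chosen after the data were seen, and the value over all chromosomes was added to the alternatives at that point.

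Genotype and strain change together in the labels of the lists. Null fish were of the NHGRI strain, maternal and paternal null embryos were crosses of Tu and NHGRI, and wild-type fish were Tu. The null sphere H3K4me1 samples, not analysed here, are labelled Tu as well, so the strain labels of null fish are not uniform. Alternatives fixed before the data were examined were a score of at least 8, a width of at least 150 bp, joining of peaks under 200 bp apart, the 10000 highest peaks of each list, and an overlap of at least 50% of the first list's peak. Each was run against 20 shifts. The 20000 widest peaks of each list were added after the data were seen, as a measure that needs no score.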

Results

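Chromatin of zebrafish sperm and early embryos was profiled by ChIP-seq to follow histone H2AZ and histone marks from the paternal gamete through genome activation, with and without anp32e. The 17 peak lists comprised 7 of H2AZ, 3 of H3K14ac, 3 of H3K4me1, 2 of H3K27ac and 1 each of H3K27me3 and H3K4me3. H2AZ formed 28300 peaks in wild-type sperm (3 libraries, 9.29 Mb), 72800 in preZGA embryos (2 libraries, 24.0 Mb) and 29589 at sphere (3 libraries, 7.33 Mb). The preZGA list thus held 2.57 times the peaks of the sperm list, 2.19 times with peaks of at least 150 bp and 17.5 times with peaks of at least 6-fold, a cut that sets the scores of separate lists on a common scale although their inputs may differ. Sperm carried 95248 peaks of H3K4me1 over 58.0 Mb, 58539 of H3K4me3 over 34.3 Mb, 28752 of H3K27me3 over 10.9 Mb and 17252 of H3K14ac over 4.35 Mb. The preZGA H3K27ac list stood apart, with 769753 peaks over 158.2 Mb, or 11.8% of the chromosomes. Chromosome 4 had the fewest peaks per Mb of all chromosomes in 15 of the 16 lists other than paternal null, for H2AZ of wild-type sperm 11.3 against 21.7 on the other chromosomes. The exception was H3K4me1 of null sperm, sparsest on chromosome 9. Each list pools its libraries, so the values have no replicate error, and the depth is unknown.

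**Figure D1:**
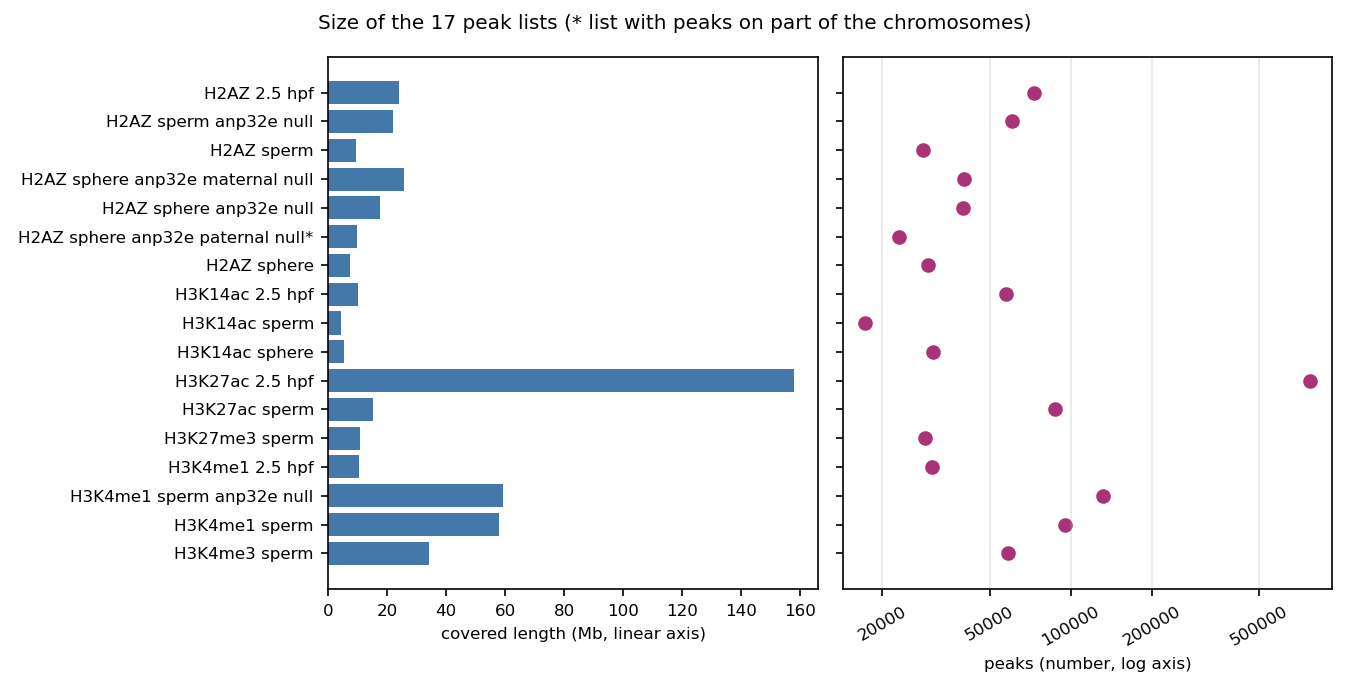
Covered length in Mb (bars, linear axis) and number of peaks (points, log axis) for each of the 17 lists, wild type where no genotype is named, with the paternal null list marked because it has peaks on part of the chromosomes. The preZGA H3K27ac list (2.5 hpf) covers 158.2 Mb, and the next longest, H3K4me1 of null sperm, covers 59.2 Mb.

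In wild-type sperm, H2AZ lay almost wholly on chromatin marked by H3K4 methylation. Of its 28300 peaks, 97.0% (95% interval 96.8 to 97.2) overlapped H3K4me1, a mark of enhancers and promoter flanks, and 92.9% (92.6 to 93.2) overlapped H3K4me3, a mark of promoters. These shares were 15.2 and 24.2 times those of shifted positions. Both marks together were found at 25705 peaks, or 90.8%, and neither at 267. H3K14ac, an acetylation mark, was present at 32.7% of H2AZ peaks (46.4 times shifted positions), and the Polycomb mark H3K27me3 at 26.3% (18.5 times). H3K27ac, a mark of active promoters and enhancers, was present at 9.89%, or 3.04 times shifted positions. The sperm H3K27ac peaks were mostly low, with a median score of 5 and 0.174% at 8 or more. They overlapped sperm H3K14ac at 4.12 times, H3K4me3 at 1.72 times and H3K4me1 at 1.60 times shifted positions, so part of this list may be background. Conversely, H2AZ was present at 23.4% of H3K4me1 peaks, 33.6% of H3K4me3 peaks, 24.0% of H3K27me3 peaks and 57.3% of H3K14ac peaks. H3K4me1 peaks with H2AZ had a median width of 1149 bp, and those without it 240 bp. For H3K4me3 the widths were 1099 and 152 bp.

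Several wide regions carried many of these marks in sperm. The widest H3K27me3 peak with H2AZ lay on chromosome 1 at 8602350 to 8610457 and also overlapped H3K4me1, H3K4me3 and H3K27ac. The next, on chromosome 2 at 21509435 to 21516939, overlapped an H3K4me3 peak of 7379 bp at 21510910 to 21518288. On chromosome 21, an H2AZ peak of 1732 bp at 23916416 to 23918147 overlapped H3K4me1, H3K4me3, H3K27me3, H3K14ac and H3K27ac. The widest sperm H3K4me3 peak, on chromosome 4 at 49279538 to 49288728, overlapped H3K14ac and had neither H2AZ nor H3K4me1. H2AZ summits lay a median of 74 bp from the nearest H3K14ac summit where the peaks overlapped, against 85 bp for H3K27ac, 98 bp for H3K27me3, 166 bp for H3K4me3 and 266 bp for H3K4me1. Peak width limits these distances, so they do not rank the marks by closeness to H2AZ. Peaks with H2AZ had median widths of 211 bp for H3K14ac, 354 bp for H3K27me3, 1099 bp for H3K4me3 and 1149 bp for H3K4me1. All sperm H3K27ac peaks had a median width of 146 bp. With the 10000 highest peaks of each list the share of H2AZ on H3K4me1 was 50.8%, still 30.1 times shifted positions.

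**Figure D2:**
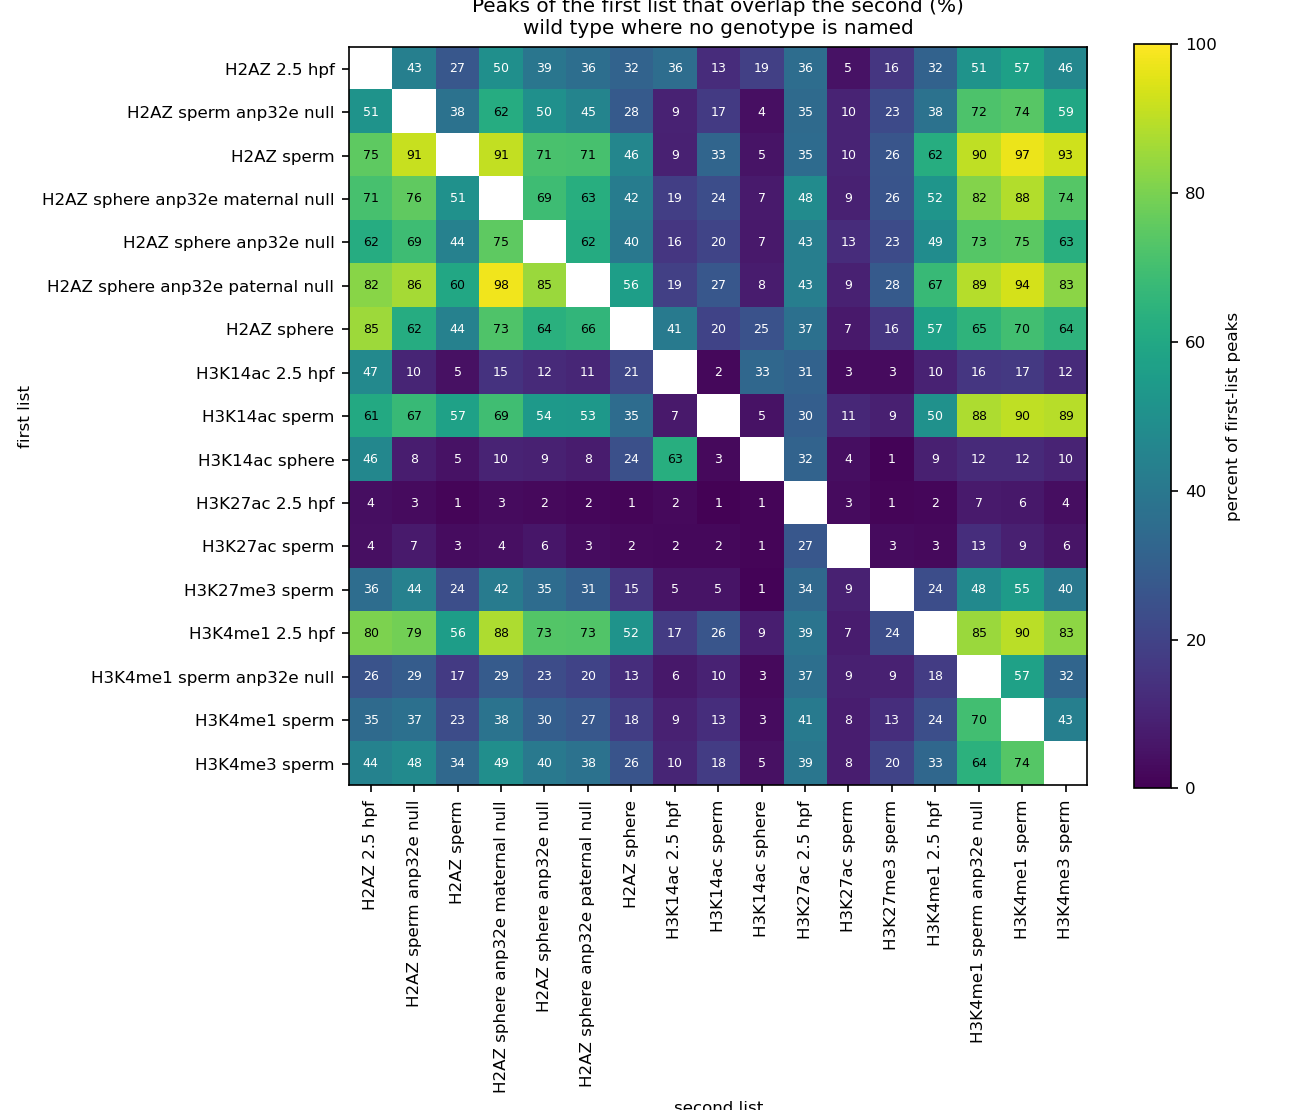
Percent of peaks of the list named at the left that overlap the list named at the bottom, for all pairs of the 17 lists, wild type where no genotype is named, with pairs of the paternal null list taken over 19 chromosomes. Wild-type sperm H2AZ shares 97.0% of its peaks with sperm H3K4me1, while sperm H3K14ac shares 6.71% with preZGA H3K14ac.

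Most places with H2AZ in sperm also had H2AZ in preZGA embryos. Of the 28300 sperm peaks, 75.2% (74.7 to 75.7) overlapped a preZGA H2AZ peak, 22.0 times the share of shifted positions, and 45.9% overlapped a sphere H2AZ peak. The marks at the site in sperm went with the share found again. It was 78.3% (77.8 to 78.8) where both H3K4me1 and H3K4me3 were present, 70.0% with H3K4me3 alone of the pair, 40.5% with H3K4me1 alone and 16.1% (11.9 to 21.1) with neither. Sites with H3K14ac in sperm were found again more often (88.6%) than sites without it (68.8%), whereas sites with H3K27me3 were found again less often (67.5%) than sites without it (78.0%). Within the sperm list the share went up with peak height, from 57.6% at scores of 4 to 5 to 93.7% at scores of 8 or more. The groups were not matched on height or width, and width by itself raises overlap. Median widths were 277 bp with both H3K4 marks, 158 bp with H3K4me3 alone, 155 bp with H3K4me1 alone and 133 bp with neither. They were 384 bp with H3K14ac and 217 bp without it, and 254 bp with H3K27me3 and 262 bp without it.

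In the preZGA embryo H2AZ was also called at many places with no peak in wild-type sperm. Of the sperm H2AZ peaks 5.95% scored 8 or more, against 40.55% of the preZGA peaks, and depth is unknown. A missing call in sperm therefore does not show that H2AZ was absent. The 52950 preZGA peaks with no sperm peak overlapped sperm H3K4me1 at 41.3% (7.06 times shifted positions) and preZGA H3K14ac at 39.8% (23.1 times). They overlapped H2AZ of null sperm at 23.1% (8.91 times). The widest of them, on chromosome 11 at 2100861 to 2103900, overlapped sperm H3K4me1, H3K4me3 and H3K27me3. The other 4 named gained regions, on chromosomes 12, 4, 19 and 23, likewise overlapped sperm H3K4me1 and H3K4me3 and a null sperm H2AZ peak. Of the 5 widest sperm H2AZ peaks with no preZGA peak, 2 were neighbours on chromosome 4, at 76320779 to 76322349 and 76322793 to 76323823. Both overlapped every mark measured in sperm and no list from embryos other than preZGA H3K27ac, which was not examined for named regions. The lost peaks on chromosomes 21 (28700392 to 28701537) and 24 (37516402 to 37517396) were again H2AZ peaks at sphere. With the 10000 highest peaks of each list the share of sperm peaks found again was 38.9%.

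**Figure D3:**
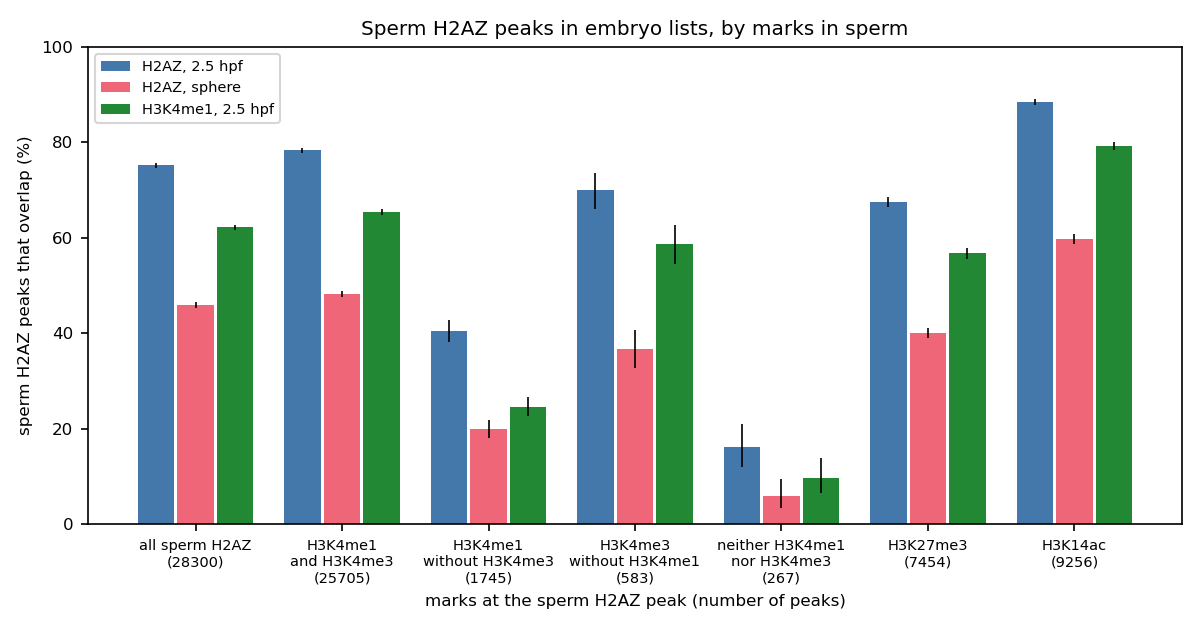
Percent of wild-type sperm H2AZ peaks that overlap preZGA H2AZ (2.5 hpf), sphere H2AZ and preZGA H3K4me1, by the marks at the peak in sperm, with the number of peaks in brackets and error bars for exact 95% intervals of counting error. The share with preZGA H2AZ is 78.3% with both H3K4me1 and H3K4me3 and 16.1% with neither.

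At sphere, H2AZ was called at a part of its preZGA sites and at few others. Of the preZGA peaks, 31.8% overlapped a sphere peak (25.9 times shifted positions), whereas 85.4% of sphere peaks overlapped a preZGA peak. Joining the 3 stages gave 79427 regions, of which 11754 (14.8%) had H2AZ at every stage, 41910 (52.8%) in preZGA alone and 573 in sperm and sphere without preZGA. Regions with H2AZ at every stage had a median width of 887 bp, and those of preZGA alone 148 bp. Joining overlapping peaks widens a region by construction, and wide peaks overlap more often. The widest lost peak, on chromosome 7 at 33077567 to 33081048, had H2AZ in sperm and overlapped H3K14ac in preZGA and sphere embryos. All 5 named lost regions had H3K14ac in both kinds of embryo and H3K4me1 in preZGA embryos. Of the 5 named gained regions, 4 had H2AZ in sperm. The exception, on chromosome 16 at 1057788 to 1058492, overlapped only preZGA H3K14ac. The share of preZGA peaks found at sphere was 5.90% with peaks of at least 6-fold, 17.6% with an overlap of at least 50% of the peak and 55.6% with the 20000 widest peaks. The 6-fold cut left 29517 preZGA and 1942 sphere peaks, so the length of the lists by itself holds that share low.

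In preZGA embryos, H3K4me1 was found mostly at H2AZ sites, while H2AZ lay partly on H3K4me1, partly on H3K14ac and often on neither. Of the 30580 H3K4me1 peaks, 80.1% overlapped H2AZ (23.0 times shifted positions) and 89.5% overlapped an H3K4me1 peak of sperm. Of the 72800 H2AZ peaks, 31.5% overlapped H3K4me1 and 35.6% overlapped H3K14ac. Both were met by 6170 peaks, or 23.8% of those on H3K14ac. Of the 46912 peaks off H3K14ac, 35.8% overlapped H3K4me1, so most of these had neither. H2AZ peaks on H3K14ac less often overlapped sperm H3K4me1 (34.4%) and sperm H2AZ (18.6%) than H2AZ peaks off H3K14ac (69.5% and 32.1%). H2AZ and H3K14ac summits lay a median of 20 bp apart where the peaks overlapped, and H2AZ and H3K4me1 summits 153 bp. The H3K14ac peaks were narrower than the H3K4me1 peaks (medians of 147 and 250 bp), which by itself shortens the distance. H2AZ peaks on H3K14ac were found again at wild-type sphere more often (42.2%) than those off it (26.1%), and these groups were not matched on width or height. The order was reversed in sphere lists of mutants. In maternal null embryos the shares were 30.9% on H3K14ac and 60.1% off it, and in null embryos 27.5% and 45.6%. With the 10000 highest peaks of each list, 51.8% of H3K4me1 peaks overlapped H2AZ.

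H3K14ac was called at largely different places in sperm and in embryos. Inputs may differ between sperm and embryo lists, and low signal in an input that embryo lists share could also place peaks. Its part in this comparison was not tested. Only 6.71% of the 17252 sperm peaks overlapped a preZGA peak, 3.68 times shifted positions, and 4.99% overlapped a sphere peak. Between the embryo stages 33.4% of preZGA peaks overlapped a sphere peak (42.3 times), and 62.5% of sphere peaks overlapped a preZGA peak. In sperm 90.4% of H3K14ac peaks lay on H3K4me1. Of preZGA peaks outside the sperm list, 15.1% lay on H3K4me1 of sperm and 8.15% on H3K4me1 of preZGA embryos. Of the 5 widest gained peaks, 4 overlapped preZGA H2AZ, among them those on chromosomes 7 (73090608 to 73092042), 1 (53911660 to 53913050) and 13 (34015156 to 34016464), which also had H2AZ and H3K14ac at sphere. The widest lost peak spanned 3957 bp on chromosome 4 at 76320141 to 76324097, over the H2AZ peaks lost there. The next, on chromosome 5 at 2422165 to 2424300, had H3K4me1, H3K4me3 and H3K27ac in sperm. From preZGA to sphere, the widest lost peak (chromosome 25, 6880281 to 6881560) overlapped only preZGA H2AZ, and the widest gained peak (chromosome 21, 13592800 to 13593688) had preZGA and sperm H2AZ. The share of sperm peaks found in preZGA embryos was 2.07% with peaks of at least 6-fold, 1.66% with the 10000 highest peaks, 1.73% with an overlap of at least 50% and 3.97% with the 20000 widest peaks. The 6-fold cut left 339 sperm H3K14ac peaks.

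Sperm H3K4me1 was found again in preZGA embryos mostly at sites with H2AZ in sperm. Of the 95248 sperm peaks, 23.9% overlapped a preZGA H3K4me1 peak, 12.4 times shifted positions. The share was 73.5% for sperm H3K4me1 peaks with H2AZ and 8.79% for those without. These groups were not matched, and peaks with H2AZ were wider (a median of 1149 against 240 bp) and higher (a median score of 11 against 7), which by itself raises overlap. The widest lost peak spanned 10001 bp on chromosome 16 at 36997684 to 37007684 and had H3K4me3, H3K14ac and H3K27ac but no H2AZ in wild-type sperm. A lost peak on chromosome 1 at 44910970 to 44919753 had the same marks, and both were present in null sperm. Among the gained peaks, those on chromosomes 10 (21554216 to 21555025), 19 (25339258 to 25340033) and 1 (11381479 to 11382228) had preZGA H2AZ, and that on chromosome 3 (45933101 to 45933857) overlapped none of the other lists examined. The share of sperm peaks found again was 12.8% with peaks of at least 6-fold, 4.49% with an overlap of at least 50%, 44.4% with the 10000 highest peaks and 59.6% with the 20000 widest.

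H3K27ac of sperm and of preZGA embryos shared little beyond shifted positions. Of the 87433 sperm peaks, 27.1% overlapped a preZGA peak, but 21.5% did so after shifts, a ratio of 1.26. The preZGA peaks overlapped preZGA H2AZ at 1.29 times, preZGA H3K14ac at 1.45 times and preZGA H3K4me1 at 1.35 times shifted positions. The widest gained peaks, on chromosomes 6 (43426849 to 43429153), 11 (2022121 to 2024093) and 13 (1133487 to 1135183), overlapped none of the other lists. That on chromosome 9 at 30966 to 32605 overlapped H2AZ and H3K14ac of preZGA and sphere embryos. Of the lost peaks, that on chromosome 4 at 76325133 to 76326033 lay beside the lost H3K14ac and H2AZ peaks named there and overlapped all other marks measured in sperm. The share of sperm peaks found again was 17.8% with peaks of at least 6-fold, 14.9% with an overlap of at least 50%, 0.860% with the 10000 highest peaks and 1.81% with the 20000 widest. The 6-fold cut left 152 sperm H3K27ac peaks.

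In sperm of anp32e null fish H2AZ was called at nearly all wild-type places and at many more. The null list held 60725 peaks over 21.8 Mb, against 28300 peaks over 9.29 Mb in wild type, a ratio of 2.34 in length. Of the wild-type peaks, 91.5% (91.2 to 91.8) overlapped a null peak, 30.9 times shifted positions. Of the 37765 peaks found in null sperm alone, 22312 lay on wild-type sperm H3K4me1 (10.2 times shifted positions). On H3K4me3 the share was 38.1% (3.45% for shifted positions) and on H3K27me3 19.4% (15.5 times), and 30.9% were H2AZ sites of wild-type preZGA embryos (10.6 times). Null peaks kept from wild type overlapped these lists more often, H3K4me1 at 98.4%, H3K4me3 at 94.7%, H3K27me3 at 27.6% and preZGA H2AZ at 85.0%. Peaks of null sperm alone were narrower (a median of 150 bp, against 232 bp for all null peaks). They were also lower (a median score of 6, against 9 in null sperm at shared peaks). Both by themselves lower overlap. The widest gained peaks lay on chromosomes 22 (24457673 to 24460237, with H3K27me3 and H3K4me3 in wild-type sperm), 16 (663970 to 665861), 5 (34961270 to 34963016), 18 (20333824 to 20335508) and 3 (32188492 to 32190173). The last 3 were H2AZ sites of wild-type preZGA and sphere embryos. The widest lost peak, on chromosome 20 at 27397572 to 27398873, had H2AZ in wild-type preZGA embryos. The length ratio was 1.59 with the 10000 highest peaks of each list, 1.74 with the 20000 widest and 13.8 with peaks of at least 6-fold, where a common cut is set on lists whose inputs may differ. With the 10000 highest, 60.7% of wild-type peaks were found. Strain differed with genotype, and the depth of both lists is unknown.

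H3K4me1 of null sperm covered about the same length as in wild type, at partly other places. It formed 131469 peaks over 59.2 Mb, against 95248 over 58.0 Mb, a length ratio of 1.02, with median widths of 264 and 343 bp. Of the wild-type peaks, 69.9% (69.6 to 70.2) overlapped a null peak, 7.93 times shifted positions. The 56216 peaks found in null sperm alone avoided wild-type preZGA H2AZ (0.506 times shifted positions) and H3K4me3 (0.668 times). They lay on H2AZ of null sperm at 4.03% (1.58 times). On wild-type sperm H3K27ac, a list with a median score of 5, they lay at 3.48 times. The 28701 wild-type peaks with no null peak lay on H3K4me3 at 20.9% (5.91 times shifted positions) and on wild-type sperm H2AZ at 4.66% (4.00 times), less often than all wild-type H3K4me1 peaks (43.1% and 23.4%). The lost peaks were narrower (a median of 153 against 343 bp) and lower (a median score of 6 against 8), which by itself lowers overlap. The null list had 1.74 times the wild-type peaks per Mb on chromosome 4 and 1.09 times on chromosomes 9 and 22. Of the 5 widest gained peaks, those on chromosomes 3 (19877561 to 19880230), 5 (35211782 to 35214180) and 4 (20475988 to 20478374) overlapped none of the other lists. The widest lost peak, on chromosome 22 at 15711448 to 15714853, had H2AZ in sperm and preZGA embryos. Gained peaks lie outside wild-type H3K4me1 by definition, which by itself lowers their overlap with marks that go with it.

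At sphere, H2AZ was called over more of the genome in null, maternal null and paternal null embryos than in wild type. In the mutants it was not called at a part of the wild-type sites. On the 19 chromosomes that the paternal null list covers, H2AZ spanned 5.49 Mb in wild type, 9.55 Mb in paternal null, 12.9 Mb in null and 18.9 Mb in maternal null embryos. The peaks numbered 22098, 22542, 29148 and 29490, and their median widths were 180, 349, 331 and 571 bp. Of the wild-type peaks, 66.0% (65.4 to 66.6) were found in paternal null, 63.5% (62.8 to 64.1) in null and 72.6% (72.0 to 73.2) in maternal null embryos. Of the paternal null peaks, 97.7% overlapped a maternal null peak, while 62.8% of maternal null peaks overlapped a paternal null peak. Over all chromosomes the null list spanned 2.39 times and the maternal null list 3.48 times the wild-type length. Wild-type preZGA H2AZ spanned 24.0 Mb, more than null sphere H2AZ (17.5 Mb) and less than maternal null (25.5 Mb). In the wild-type sphere list 6.56% of peaks scored 8 or more, against 60.7% in maternal null. Depth is unknown, so a difference in depth or enrichment between the lists was not separated from genotype. At peaks shared with wild type, the maternal null list was a median of 2.51 times as high by the authors' scores, if those of separate lists can be compared, and the other mutant lists give no score. The track name of the maternal null list holds the word Repeated, and whether it comes from a repeat experiment is unknown. The value over all chromosomes for paternal null, 50.2%, counts wild-type peaks on chromosomes where the paternal list has none.

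H2AZ peaks gained in the mutant embryos fell on H2AZ sites of sperm and preZGA embryos more often than shifted positions did, though many lay elsewhere. Those of null embryos overlapped null sperm H2AZ at 52.3% (18.5 times shifted positions), wild-type sperm H2AZ at 24.65% (19.6 times) and wild-type preZGA H2AZ at 40.0% (12.3 times), below the shares of all null sphere peaks (68.8%, 44.1% and 62.0%). Those of maternal null embryos overlapped the same lists at 63.1%, 32.7% and 53.1% (75.8%, 50.8% and 70.9% for all maternal null peaks), and those of paternal null embryos, on 19 chromosomes, at 78.8%, 44.2% and 66.2% (86.4%, 60.01% and 82.0% for all paternal null peaks). Of all wild-type sphere peaks, 85.4% overlapped preZGA H2AZ. Gained peaks lie outside wild-type sphere peaks by definition, which by itself lowers their shares below those of all mutant peaks. Those of maternal null embryos were also narrower, with a median of 296 bp against 566 bp for all maternal null peaks. A gained peak on chromosome 7 was among the widest in null (32324943 to 32327770) and in maternal null embryos (32324976 to 32327824), and it had H2AZ in null sperm and wild-type preZGA embryos but not in wild-type sperm. The widest peak gained in paternal null embryos lay on chromosome 13 at 32863432 to 32865309 and was also present in null and maternal null embryos. In joined regions of the 19 chromosomes, 11153 of 42013 (26.6%) had H2AZ in all 4 genotypes and 5267 (12.5%) in the 3 mutants without wild type. All 3 mutants were set against the same wild-type list, so part of that sharing may come from the shared control.

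Wild-type sphere sites that lacked H2AZ in the mutants were mostly sites of H3K14ac. Of the 8134 wild-type peaks with no maternal null peak, 86.4% overlapped preZGA H3K14ac (60.1 times shifted positions) and 68.4% overlapped sphere H3K14ac (91.3 times). They overlapped wild-type sperm H2AZ at 0.307% and preZGA H3K4me1 at 0.922%, both below the mean of shifted positions, but this did not hold in the other mutants. Peaks with no null peak overlapped these lists at 12.3% (11.8 times shifted positions) and 14.6% (12.6 times), and peaks with no paternal null peak at 6.68% (6.33 times) and 8.75% (7.57 times). For peaks with no null peak the share on preZGA H3K14ac was 69.5%, and for peaks with no paternal null peak it was 74.6%. Among all wild-type sphere peaks it was 40.8%. The widest sites did not all follow this, since embryo H3K14ac was found at 1 of the 5 widest lost in null, 3 of those lost in maternal null and 5 of those lost in paternal null embryos. The widest, on chromosome 4 at 53829164 to 53830722, lacked H2AZ in null and maternal null embryos, had it in wild-type preZGA embryos and had no embryo H3K14ac. The sites on chromosomes 13 (38877757 to 38878473) and 19 (39387646 to 39388297) lacked H2AZ in null, maternal null and paternal null embryos and had H3K14ac in wild-type preZGA and sphere embryos. The peaks with no maternal null peak were narrow, with a median of 139 bp against 180 bp for all wild-type sphere peaks. Low signal in an input that wild-type embryo lists share could also place H2AZ and H3K14ac together. It was not tested for these sites. H3K14ac of the mutants was not analysed here. Strain differs with genotype in these comparisons too.

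**Figure D4:**
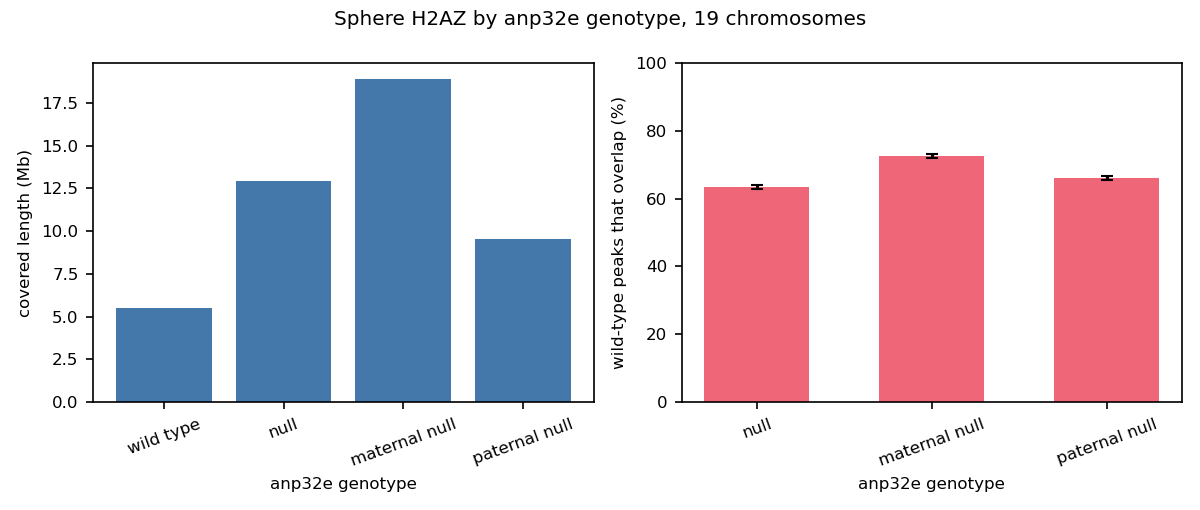
Sphere H2AZ on 19 chromosomes by anp32e genotype, as covered length in Mb (left, bars) and as the percent of wild-type peaks that overlap each mutant list (right, bars with exact 95% intervals of counting error). Covered length runs from 5.49 Mb in wild type to 18.9 Mb in maternal null embryos, and 63.5% to 72.6% of wild-type peaks are found in the mutants.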

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

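The list of preZGA H3K27ac held peaks off the chromosomes, which no comparison used. A peak of 16641 bp covered the whole mitochondrial sequence, and another of 5457 bp covered the whole sequence of PhiX, a phage genome used as a sequencing control. The sperm H3K27ac list had a mitochondrial peak of 114 bp. None of the other lists had peaks off the chromosomes.

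The number of preZGA H3K27ac peaks (769753 against 87433 in sperm) was weighed with tests written before their results were seen. If wide acetylated domains had been broken into pieces, joining peaks under 200 bp apart would lower the number by more than 50%, but it fell by 9.62%. If few reads had turned background into peaks, even the higher peaks would ignore other acetylation of the stage, and peaks of score 8 or more overlapped preZGA H3K14ac at only 1.56 times shifted positions. Calls from background may therefore account for much of this list. Scores of this list were uneven, with 38.3% of peaks at 6, 2.15% at 7 and 14.7% at 8, and the cause was not tested. The overlap value does not tell background from a true spread of H3K27ac over the early genome. Such a spread could also overlap H3K14ac at close to shifted positions. That biological explanation was not tested and stays open.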

How the results depend on the processing

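The 20000 widest peaks were added after the data were seen, as was the value over all chromosomes for paternal null, when the limit to 19 chromosomes was chosen. The other alternatives were fixed before. For 16 results, 86 alternatives were run. No share or ratio crossed the level of shifted positions or of 1, 12 values stayed within the interval of the main value (a ratio within 1.5 times) and 74 moved outside it. Leaving H3K27ac aside, the shares stayed 2.86 to 192 times those of shifted positions. For sperm H3K27ac in preZGA embryos the ratio stayed between 1.2 and 1.55. The intervals are narrow because the lists are long. Except for the value over all chromosomes, the cause was not tested.

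The 6-fold cut left 29517 preZGA and 1942 sphere H2AZ peaks of wild type, 339 sperm H3K14ac peaks and 152 sperm H3K27ac peaks. With peaks of at least 6-fold, the shares were for sperm H2AZ on H3K4me1 98.2%, sperm H2AZ found in preZGA 77.2%, preZGA H2AZ found at sphere 5.90%, sperm H3K14ac found in preZGA 2.07% and preZGA H3K14ac found at sphere 27.7%. Other shares were for sperm H3K4me1 found in preZGA 12.8%, sperm H3K27ac found in preZGA 17.8%, preZGA H3K4me1 on H2AZ 85.7% and wild-type H2AZ found in null sperm 96.0%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 75.3% and wild-type sphere H2AZ found in maternal null 52.2%. With peaks of at least 150 bp, the shares were for sperm H2AZ on H3K4me1 97.5%, sperm H2AZ found in preZGA 76.8%, preZGA H2AZ found at sphere 32.6%, sperm H3K14ac found in preZGA 5.54% and preZGA H3K14ac found at sphere 30.7%. Other shares were for sperm H3K4me1 found in preZGA 26%, sperm H3K27ac found in preZGA 25.1%, preZGA H3K4me1 on H2AZ 85.3% and wild-type H2AZ found in null sperm 92.5%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 73.4%, wild-type sphere H2AZ found in null 73.6%, wild-type sphere H2AZ found in maternal null 82.8% and wild-type sphere H2AZ found in paternal null 77.2%. With peaks under 200 bp apart joined, the shares were for sperm H2AZ on H3K4me1 97.2%, sperm H2AZ found in preZGA 76.6%, preZGA H2AZ found at sphere 33.7% and sperm H3K14ac found in preZGA 7.45%. Other shares were for sperm H3K4me1 found in preZGA 26.4%, sperm H3K27ac found in preZGA 27.6% and wild-type H2AZ found in null sperm 92.0%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 71.9%, wild-type sphere H2AZ found in null 62.1%, wild-type sphere H2AZ found in maternal null 70.2% and wild-type sphere H2AZ found in paternal null 64.4%. With the 10000 highest peaks, the shares were for sperm H2AZ on H3K4me1 50.8%, sperm H2AZ found in preZGA 38.9%, preZGA H2AZ found at sphere 41.4%, sperm H3K14ac found in preZGA 1.66% and preZGA H3K14ac found at sphere 49.1%. Other shares were for sperm H3K4me1 found in preZGA 44.4%, sperm H3K27ac found in preZGA 0.860%, preZGA H3K4me1 on H2AZ 51.8% and wild-type H2AZ found in null sperm 60.7%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 65.8% and wild-type sphere H2AZ found in maternal null 57.1%. With an overlap of at least 50% of the peak, the shares were for sperm H2AZ on H3K4me1 92.8%, sperm H2AZ found in preZGA 54.5%, preZGA H2AZ found at sphere 17.6%, sperm H3K14ac found in preZGA 1.73% and preZGA H3K14ac found at sphere 29.4%. Other shares were for sperm H3K4me1 found in preZGA 4.49%, sperm H3K27ac found in preZGA 14.9%, preZGA H3K4me1 on H2AZ 68.2% and wild-type H2AZ found in null sperm 87.2%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 62.1%, wild-type sphere H2AZ found in null 58.6%, wild-type sphere H2AZ found in maternal null 71.9% and wild-type sphere H2AZ found in paternal null 62.4%. With the 20000 widest peaks, the shares were for sperm H2AZ on H3K4me1 71.0%, sperm H2AZ found in preZGA 62.2%, preZGA H2AZ found at sphere 55.6%, sperm H3K14ac found in preZGA 3.97% and preZGA H3K14ac found at sphere 44.8%. Other shares were for sperm H3K4me1 found in preZGA 59.6%, sperm H3K27ac found in preZGA 1.81%, preZGA H3K4me1 on H2AZ 72.0% and wild-type H2AZ found in null sperm 76.2%. In mutants, the shares were for wild-type H3K4me1 found in null sperm 71.9%, wild-type sphere H2AZ found in maternal null 73.6% and wild-type sphere H2AZ found in paternal null 67.3%. The covered length of H2AZ in null over wild-type sperm was 13.8 and the peaks of preZGA over sperm H2AZ were 17.5 with peaks of at least 6-fold, a common cut on scores of lists whose inputs may differ. The length ratio was 1.59 with the 10000 highest peaks and 1.74 with the 20000 widest. The share of wild-type sphere H2AZ found in paternal null embryos over all chromosomes was 50.2%, lower by construction because that list has no peaks on 5 chromosomes.

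No paired analysis was possible because each list pools its replicates and no result comes from a test. Leaving out a replicate and using the replicate number as a block were not possible for the same reason. The 6-fold and 10000-peak settings gave no value for null and paternal null sphere embryos, whose lists give no score. Settings fixed in advance for the promoter window, the transcript start, the covered part of the window, the gene lists and their matching on CpG count were not run, since no annotation of the lists' build was used here. Depth, which is unknown, limits every comparison of how much was called.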

Other observations

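Both tests of a shared input in this part were added after related overlaps were seen, that of most places after its own result, and the heights of maternal null embryos were taken up after they were seen. The other tests were chosen before. In wild-type sperm, H3K27me3 peaks with H2AZ were more often H2AZ sites in preZGA embryos (73.9%) and at sphere (43.2%) than H3K27me3 peaks without it (24.0% and 6.70%). For H3K14ac peaks of sperm the preZGA shares were 83.5% with H2AZ and 30.2% without. Peaks with and without H2AZ were not matched, and those with it were wider (medians of 354 against 178 bp for H3K27me3 and 211 against 152 bp for H3K14ac). Of sperm H3K27me3 peaks, 40.4% overlapped sperm H3K4me3, 10.2 times shifted positions.

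The larger number of H2AZ peaks in null sperm has several explanations. Calls at random places are argued against as the only source of the gain. Peaks of null sperm alone overlapped wild-type sperm H3K4me1 at 10.2 times shifted positions. Such calls stay open for a part of these peaks, since many lay off H3K4me1, where the test does not decide. A uniformly higher enrichment of the null libraries at the same sites may account for the pattern, because only 1.39% of peaks of null sperm alone rose above the height that the 95th percentile of the gain at shared peaks allows. The median gain there, 1.995 times, allows a score under 8, and 17.7% of these peaks had 8 or more, so the outcome rests on the percentile, which was fixed before. Nor does such a gain by itself account for the 2407 wild-type peaks not found in null sperm. These were low and narrow, so they say little against it. Their median score was 5, against 6 for shared peaks, and their median width 148 bp, against 260 bp for all wild-type peaks. Of shared sperm H3K4me1 peaks, 28.5% were higher in null sperm and 49.5% lower, with a median ratio of 1. Higher scores were thus not general to the null sperm lists. A gain confined to the H2AZ libraries stays open. For maternal null sphere embryos the same measure, the share of gained peaks above that height, gave 4.91%. A uniform gain by itself does not account for the 8134 wild-type peaks lost there. Their median score of 6 was that of the shared peaks. Their median width was 139 bp, against 180 bp for all wild-type sphere peaks. The measure of gained peaks, like the 6-fold cut, sets the authors' scores of separate lists on a common scale, which separate inputs could distort. A strain difference cannot be told apart from genotype, since the labels name 0 wild-type libraries of the NHGRI strain (null sphere H3K4me1 samples, not analysed here, are labelled Tu), and loss of the chaperone, the biological explanation, stays open beside it.

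The sharing of preZGA H2AZ with H3K14ac, with summits a median of 20 bp apart, could come from low signal in an input that the embryo lists share. Such places would then also be called for H3K4me1 of the same stage. H2AZ peaks on H3K14ac overlapped preZGA H3K4me1 at 23.8%, 15.7 times shifted positions. Peaks off it did so at 35.8%, but 69.5% of these lie on sperm H3K4me1, so the lower share on H3K14ac does not decide. Of the 16985 H2AZ peaks on H3K14ac and away from sperm H3K4me1, 0.707% overlapped preZGA H3K4me1, so few of these places were also called for H3K4me1. This share does not decide whether a shared input is the cause at most of these places. Leaving out sperm H3K4me1 by itself lowers it, since 89.5% of preZGA H3K4me1 peaks lie there. Its rule was also set after the value was seen, and it needs H3K4me1 to have been set against the same input. The sources used here do not say which input was used. A shared input stays open. Of these 16985 peaks, 101 met preZGA H3K4me1 peaks that also lie outside sperm H3K4me1, 7.05 times shifted positions. Whether H2AZ and H3K14ac lie on the same nucleosomes of wild-type embryos, the biological explanation, was not tested.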
